A study of Mus musculus with 6 samples.

How the data were processed

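Total RNA was sequenced from Hepa1-6 cells, a mouse hepatoma line used as a liver cell model, after 3 days of siRNA knockdown with the lipid reagent Lipofectamine RNAiMAX. Per the labels, 3 libraries came from cells given an siRNA against Renilla luciferase, a sequence mouse cells lack, and 3 from cells given siRNA against Crebl2. Cells grew in a medium with 4.5 g/L glucose and 10% serum, and libraries were made with a stranded total RNA kit. Groups and replicate numbers were taken from the labels, which do not say whether the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

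The deposited values are raw read counts per Ensembl transcript, 58611 rows per library, with no normalisation by the authors. Trim Galore, TopHat and HTSeq are named in the submitters' processing notes, without versions, roles or settings, as are the builds mm9 and GRCm38. Total counts per library ran from 27082572 to 29158489, and each file held the same rows. The test by gene, the gene lists, the rule for named genes and, unless said otherwise, the alternative settings were chosen before the data were examined. Of the 58611 transcript identifiers, 58264 matched GENCODE M21 (GRCm38), 53484 of them with the same version, and 347 did not. Unmatched rows held at most 0.0497% of a library's counts and were kept as features of their own that are never named.

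Reads that fall on several transcripts were apparently not counted. The 9603 rows whose transcripts have no exonic base of their own held 0.0235% of all counts. Gapdh, which has many overlapping transcript models, had 16 counts over the 6 libraries and Rps6 had 258. A deposited count therefore reflects the bases unique to 1 transcript, and 3501 of 21782 protein-coding genes have under 200 such bases in their main row. Counts of different genes are not comparable as abundances, while the same gene can be compared between libraries. Whether strand was used in counting is not given in the sources used here. Of 214 rows whose bases are shared only with a transcript on the other strand, 1.40% held 60 or more counts, against 35.4% of rows with at least 200 bases of their own. Genes with antisense partners or near-identical copies, among those named Cyp21a1, Ifi27l2a, Ifi27l2b, Eef1a1, Pgk1, Pgam1 and the histone genes, are uncertain for that reason.

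The deposited counts were summed per gene, because the comparison had been designed by gene. Of 8675 genes with at least 300 counts, 94.5% drew over 90% of their counts from 1 row, so the sum is mostly that row. The rows tested singly were an added alternative. Genes were tested with the quasi-likelihood test of edgeR 4.0.16 under R 4.3.3, two-sided, with TMM scaling, the filterByExpr filter and Benjamini-Hochberg adjustment, and called at an adjusted p under 0.05. The filter kept 11616 genes. Standard errors (SE) of log2 fold changes were derived from the fold change and its test statistic. CPM values were computed here from the deposited counts with TMM-scaled library sizes. Counts behind low ratios are given with a 95% exact binomial interval, which covers counting error only, since reads without molecular identifiers are not independent molecules.

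The 39 gene lists came from textbook pathways and include markers of cell types the culture could hold. The 35 lists with at least 5 tested members were tested with camera in limma 3.58.1, two-sided, on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over lists. An estimated correlation and fry, which asks whether a list's genes move on balance one way, were run beside it. Shares of library counts were compared by an exact two-sided permutation test, whose smallest p with 3 against 3 is 0.1.

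Named genes followed a rule. It takes Crebl2, the 10 largest rises and 10 largest falls, and the 5 smallest p per direction, among called genes with groups that do not overlap and a mean CPM of at least 1. Gene models without a proper symbol and pseudogenes were passed over. It adds up to 4 called members per list with the smallest p, the 1 with the smallest p where none was called, and Crebrf and Crebzf in any case. That gave 173 genes, of which the text names those its comparisons need. Other genes are named only where said to be chosen after their values were seen.

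The procedure was tested on counts simulated from these libraries, with 200 of 11616 genes changed. edgeR recovered 68.7% of genes changed 1.5-fold, 91.0% of those changed 2-fold and 98.5% of those changed 4-fold, and 9.95% of its 191 calls were false, above the nominal level. DESeq2 1.42.0 recovered 64.2%, 83.6% and 92.4%, with 4.76% of 168 calls false. Far more genes, 4518, were called in the libraries themselves, where the adjustment sets a looser cutoff, so these shares do not carry over to them. Camera called the shifted list and 0 of 20 unchanged lists. Genes were drawn independently of each other, so this could not test false list calls that arise from correlation between genes.

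Alternative settings were RLE, upper quartile and library size scaling, no filter and a filter of 1 CPM in 3 libraries, DESeq2, limma-voom with and without sample weights, the replicate number as a block, a GC and length offset with and without that block, removal of mitochondrial and small structural RNA genes, a test against a 1.2-fold change, a protein-coding denominator for library shares, and each library left out in turn. Transcript rows, the mitochondrial share as a covariate and removal of genes with a certain 3' UTR word were added after seeing the data. Words of 7 bases were counted in the annotated 3' UTRs of 9743 tested genes, and a regression on 3' UTR length and base content gave each of 15270 words a z score, with fold changes limited to 2 on the log2 scale. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 were used for these steps.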

Results

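Gene expression was measured by RNA sequencing in 6 libraries of Hepa1-6 hepatoma cells, 3 from cells treated with control siRNA and 3 from cells treated with Crebl2 siRNA for 3 days. Total counts were 29158489, 28477181 and 27385328 in the control libraries and 27710914, 27082572 and 27296518 in the Crebl2 siRNA libraries. The design holds 1 comparison, which asks how expression in a liver cell line, that of metabolic genes in particular, differs once Crebl2, a basic leucine zipper protein related to the CREB transcription factors, is depleted. The first principal component of log2 CPM held 60.3% of the variance and separated the groups.

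Crebl2 mRNA was lower in each Crebl2 siRNA library than in any control library. The gene lies on the plus strand of chromosome 6 (134830154 to 134858931, GRCm38), and its counts all fell on its protein-coding transcript of 3629 bases, of which 3017 are unique to it. Control libraries held 3248, 3162 and 3041 counts and Crebl2 siRNA libraries 813, 826 and 896. Expression was 113 ± 0.858 CPM (SD, n = 3) in controls and 30.4 ± 1.69 CPM (SD, n = 3) after knockdown, a log2 fold change of -1.90 (SE 0.0582; edgeR adjusted p = 2.83e-12). The remaining level was 26.9% of control (95% interval 24.8 to 29.1%), and Crebl2 had the smallest p of all genes tested. The exact permutation test of log2 CPM gave p = 0.1, the smallest that 3 against 3 libraries allow. Of the related factors, Crebzf fell (log2 fold change -0.27, edgeR adjusted p = 0.0022), whereas Crebrf had a log2 fold change of -0.02 (edgeR adjusted p = 0.858).

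The response was broad and mostly small in size. Of 11616 genes tested, 4518 changed, 2180 upward and 2338 downward, at an adjusted p under 0.05 by edgeR. Among them 71.5% changed by under 1.5-fold, and 448 changed at least 2-fold, 236 upward and 212 downward. With library size alone as the scaling, 2741 rose and 1920 fell, so the balance of directions depends on the scaling, with 58.8% of calls upward against 48.3% under TMM. The groups did not overlap for 48.8% of all tested genes, where chance gives 10%.

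**Figure D1:**
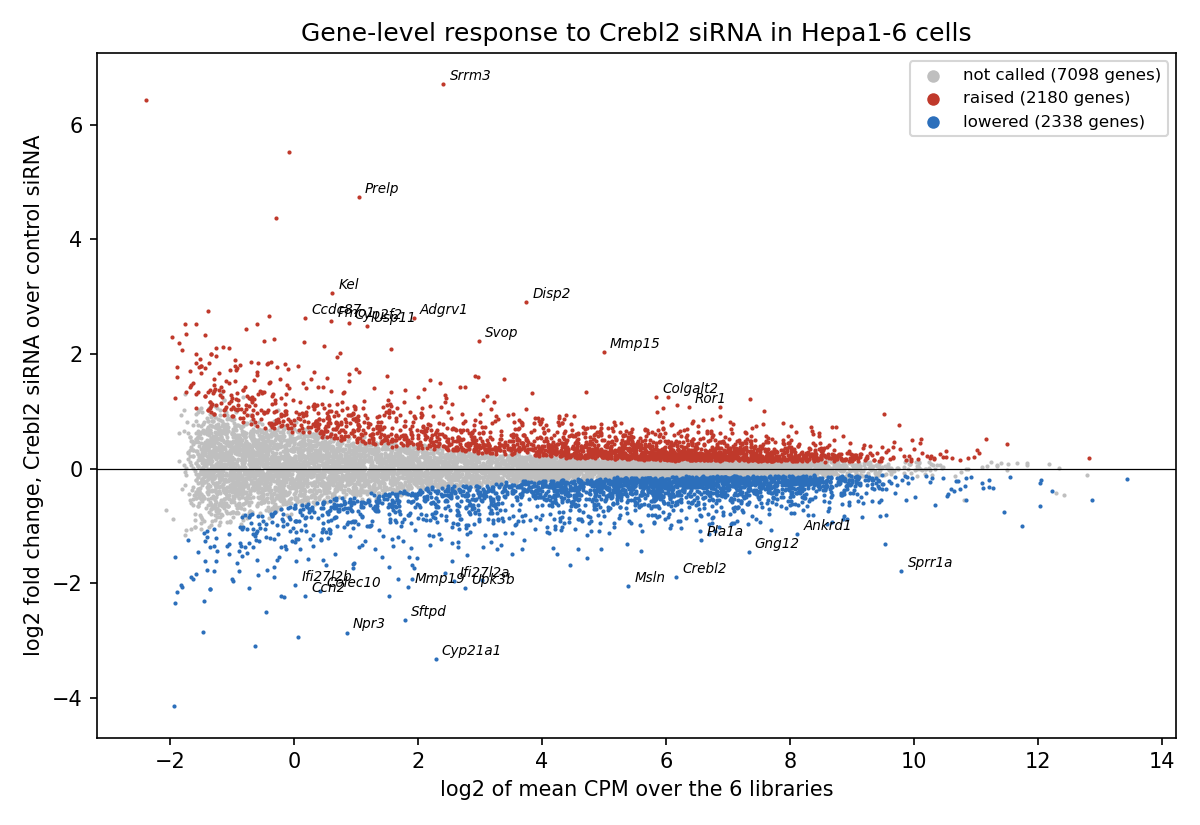
Each point is 1 of the 11616 genes tested, with the log2 of its mean CPM over the 6 libraries on the x axis and its log2 fold change, Crebl2 siRNA over control siRNA, on the y axis. Red points are the 2180 genes raised and blue points the 2338 lowered, and labels mark Crebl2, the largest changes and the smallest p among the named genes.

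Among called genes with groups that did not overlap, a mean of at least 1 CPM and a proper symbol, the steepest falls were in Cyp21a1, Npr3 and Sftpd. Cyp21a1, which encodes steroid 21-hydroxylase and has a near-identical pseudogene copy, fell from 8.86 ± 0.335 to 0.875 ± 0.217 CPM (SD, n = 3 each; log2 fold change -3.33, SE 0.161). Next came the natriuretic peptide clearance receptor Npr3 (-2.86), surfactant protein D (Sftpd, -2.65), the matricellular protein Ccn2 (-2.23), the liver collectin Colec10 (-2.14), uroplakin Upk3b (-2.08), the metalloproteinase Mmp19 (-2.07) and mesothelin (Msln, -2.06). The interferon-inducible pair Ifi27l2b (-2.04) and Ifi27l2a (-1.96) completed the 10 largest falls of that set. Several of these rest on few reads. Npr3 had 265 counts summed over the controls and 36 after knockdown, a ratio of 0.136 (95% interval 0.0932 to 0.193), and Ccn2 had 156 and 33, a ratio of 0.212 (0.141 to 0.310). Falls with the smallest p, apart from Crebl2, were in the cornified envelope protein Sprr1a (1376 ± 89.4 to 396 ± 19.2 CPM, log2 fold change -1.80), the G protein subunit Gng12 (-1.46), the YAP-responsive Ankrd1 (-1.15) and the phospholipase Pla1a (-1.25), each with an edgeR adjusted p of 1.64e-10 or lower.

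The steepest rise of the same set was in Srrm3, a splicing factor of neurons and sensory cells. It had 1 to 5 counts per control library and 277 to 310 per Crebl2 siRNA library, a ratio of 110 (95% interval 55.5 to 255). Disp2, a dispatched family membrane protein expressed in brain, rose from 3.14 ± 0.263 to 23.6 ± 0.94 CPM (SD, n = 3 each; log2 fold change 2.91, SE 0.0996), and Svop, a synaptic vesicle protein, by 2.23 on the log2 scale. Prelp, a leucine-rich matrix proteoglycan, had 12 control counts and 331 after knockdown, a ratio of 27.6 (15.6 to 54.0). The blood group protease Kel (3.06), the adhesion receptor Adgrv1 (2.63), Ccdc87 (2.62), the flavin monooxygenase Fmo1 (2.58), the cytochrome P450 Cyp2f2 (2.53) and the deubiquitinase Usp11 (2.48) completed the 10 largest rises of that set in log2 fold change, these 6 from a control mean of at most 1.05 CPM. Among better expressed genes the smallest p belonged to the membrane metalloproteinase Mmp15 (12.5 ± 1.24 to 51.2 ± 2.6 CPM, log2 fold change 2.04), the collagen galactosyltransferase Colgalt2 (1.25) and the receptor Ror1 (1.07), each with an edgeR adjusted p of 3.93e-10 or lower.

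**Figure D2:**
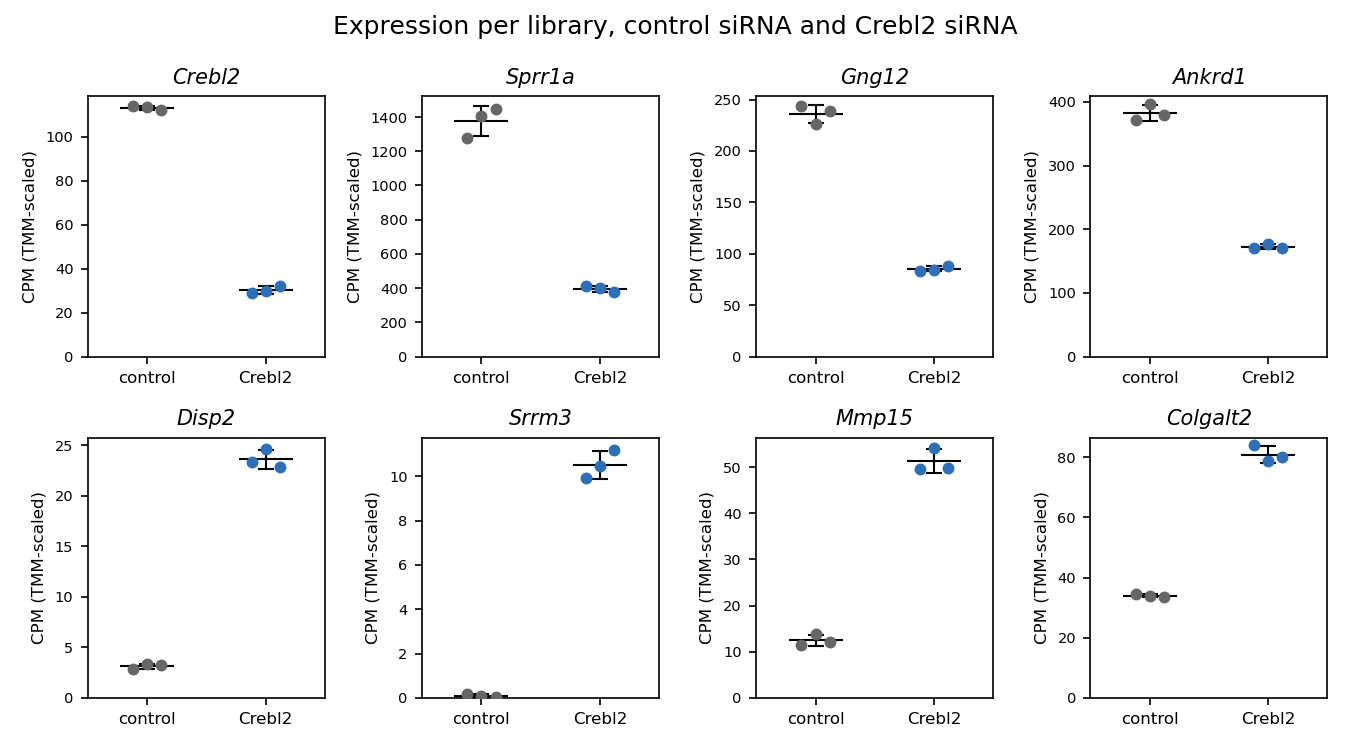
Each panel shows 1 gene, with TMM-scaled CPM on a linear y axis starting at 0 and the control and Crebl2 siRNA groups on the x axis. Points are the 3 libraries of a group, and lines with bars are the mean and SD. Crebl2, Sprr1a, Gng12 and Ankrd1 were lower, and Disp2, Srrm3, Mmp15 and Colgalt2 higher, in every Crebl2 siRNA library than in any control library.

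Genes of sterol synthesis were lowered nearly throughout. Of 22 tested members of the cholesterol synthesis and uptake list, 19 fell and 3 did not pass the test (20 lowered when adjusted over the list alone), with a median log2 fold change of -0.58. Cyp51, the lanosterol demethylase, fell by 0.78 on the log2 scale (326 to 190 CPM), and the sterol oxidase Msmo1 by 0.80, the dehydrogenase Nsdhl by 0.81 and the sterol carrier Stard4 by 0.91. The list lay below the other genes by camera (adjusted p = 2.38e-09; adjusted p = 0.25 with an estimated correlation). Of 28 fatty acid and triglyceride synthesis genes, 13 fell and 3 rose (14 and 3 when adjusted over the list alone; camera adjusted p = 0.00716; adjusted p = 0.314 with an estimated correlation). Those lowered included the acyltransferase Agpat2 (log2 fold change -1.12), the desaturases Fads1 (-0.68) and Scd1 (-0.64) and the mitochondrial citrate carrier Slc25a1 (-0.59).

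Several genes of glycogen and glucose metabolism fell. Among 13 genes of gluconeogenesis and glycogen, 6 fell and 1 rose (8 and 1 when adjusted over the list alone), the list was called lower by camera (adjusted p = 0.00922; adjusted p = 0.314 with an estimated correlation), and its median log2 fold change was -0.35. Its lowered members included the glycogen-targeting subunit Ppp1r3c (log2 fold change -0.60), the UDP-glucose pyrophosphorylase Ugp2 (-0.66), the alanine transaminase Gpt2 (-0.55) and the mitochondrial carboxykinase Pck2 (-0.42). Of 23 glycolysis and glucose uptake genes, 10 fell (10 when adjusted over the list alone), among them Pgk1 (-0.65), Pgam1 (-0.46), Pfkl (-0.45) and the glucose transporter Slc2a1 (-0.42), while the list as a whole was not called (camera adjusted p = 0.0656). It was called in 8 of 19 alternative settings, whose camera adjusted p ran from 0.0124 to 0.0999. These were the runs without control replicate 1 (0.0124), Crebl2 siRNA replicate 2 (0.0445) or Crebl2 siRNA replicate 3 (0.0477), with no filter (0.0202) or a 1 CPM filter (0.0266), with limma-voom (0.0285) and its sample weights (0.0207), and without genes that hold a 3' UTR word (0.0344).

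Many hypoxia, inflammatory and matrix genes fell. Of 14 hypoxia response genes, 11 fell (12 when adjusted over the list alone), including Epas1, which encodes HIF-2 alpha (log2 fold change -1.32), the prolyl hydroxylases P4ha1 (-1.16) and Egln3 (-0.78), and Bnip3 (-0.89), with a camera adjusted p of 6.84e-05 (adjusted p = 0.324 with an estimated correlation). Of 18 NF-kB and acute phase genes, 12 fell and 2 rose, and the counts were equal when adjusted over the list alone. The chemokine Ccl2 fell from 13.0 to 3.38 CPM (log2 fold change -1.94), the adhesion molecule Icam1 changed by -0.49 and the inhibitor Nfkbie by -0.85 (camera adjusted p = 0.000397; adjusted p = 0.224 with an estimated correlation). Of 25 TGF-beta, YAP and extracellular matrix genes, 15 fell and 2 rose, again with equal counts when adjusted over the list alone, and Mmp14 (-0.83) and Ccn1 (-0.71) were among those lowered (camera adjusted p = 0.000397; adjusted p = 0.296 with an estimated correlation). Immediate early genes followed, with 12 of 22 lowered and 2 raised, the same counts when adjusted over the list alone, and examples in the phosphatase Dusp1 (-1.09), Junb (-0.98) and Klf4 (-0.68) (camera adjusted p = 0.00731; adjusted p = 0.314 with an estimated correlation).

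The ATF4 and amino acid list was split. Of 28 members, 15 fell and 5 rose (16 and 5 when adjusted over the list alone), and it was called lower by camera (adjusted p = 0.00922; adjusted p = 0.53 with an estimated correlation). The pseudokinase Trib3 (log2 fold change -1.02), the glutathione-degrading Chac1 (-1.41) and Cebpb (-0.46) fell, whereas Sesn2 (0.47) and the cystine transporter Slc7a11 (0.59) rose. Of 38 lysosome and autophagy genes, 16 fell (16 when adjusted over the list alone), among them the protease Ctsl (-0.64), Wipi1 (-0.59), the kinase Ulk2 (-0.55) and Map1lc3b (-0.45), at a camera adjusted p of 0.000397 (adjusted p = 0.314 with an estimated correlation). Of 17 hepatocyte identity and plasma protein genes with enough counts, 8 fell and 2 rose (9 and 2 when adjusted over the list alone; camera adjusted p = 0.011; adjusted p = 0.314 with an estimated correlation). Complement C3 went from 1048 to 423 CPM (log2 fold change -1.31), fibrinogen Fgb changed by -1.41, the transcription factor Foxa3 by -0.81 and transferrin (Trf) by -0.42.

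Genes of cell division rose. Of 31 DNA replication and S phase genes, 21 rose (22 when adjusted over the list alone), among them cyclin E (Ccne1, log2 fold change 0.70), E2f2 (1.04), the clamp loader subunit Rfc5 (0.47) and Pcna (0.43). The list lay above the other genes (camera adjusted p = 4.2e-07, and adjusted p = 0.109 with an estimated correlation). Of 33 mitosis genes, 22 rose and 1 fell, with equal counts when adjusted over the list alone, and separase (Espl1, 0.66), the kinetochore protein Spc24 (0.95), Bub1b (0.50) and Top2a (0.50) were among those raised (camera adjusted p = 1.56e-06; adjusted p = 0.314 with an estimated correlation). Of 25 pentose phosphate and nucleotide synthesis genes, 13 rose and 2 fell, the same counts when adjusted over the list alone, with the ribonucleotide reductase subunits Rrm2 (0.62) and Rrm1 (0.44) and the folate enzyme Mthfd1 (0.43) raised (camera adjusted p = 0.00214; adjusted p = 0.314 with an estimated correlation). All 5 replication-dependent histone genes with enough counts rose (5 when adjusted over the list alone), at a camera adjusted p of 0.00107 (adjusted p = 0.314 with an estimated correlation), but Hist2h4 rested on 16 control and 94 knockdown counts and Hist1h1e on 8 and 42. Hist1h2bc rose by 1.32 on the log2 scale, from 8.21 to 20.5 CPM.

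Smaller rises ran through ribosome assembly and the proteasome. Of 34 ribosome biogenesis genes, 21 rose (24 when adjusted over the list alone), including Utp20 (log2 fold change 0.44), Polr1c (0.39), Gar1 (0.36) and nucleolin (Ncl, 0.33), at a camera adjusted p of 6.55e-05 (adjusted p = 0.25 with an estimated correlation). Of 29 proteasome subunits, 13 rose (16 when adjusted over the list alone), by 0.30 for Psmc5 and 0.27 for Psmb7 (camera adjusted p = 0.00167; adjusted p = 0.314 with an estimated correlation). Cytoplasmic ribosomal protein genes showed 1 raised and 4 lowered of 45, the same when adjusted over the list alone, and were not called as a list (camera adjusted p = 0.803). Their median log2 fold change was 0.02, against a mean of -0.03 and a downward test.

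**Figure D3:**
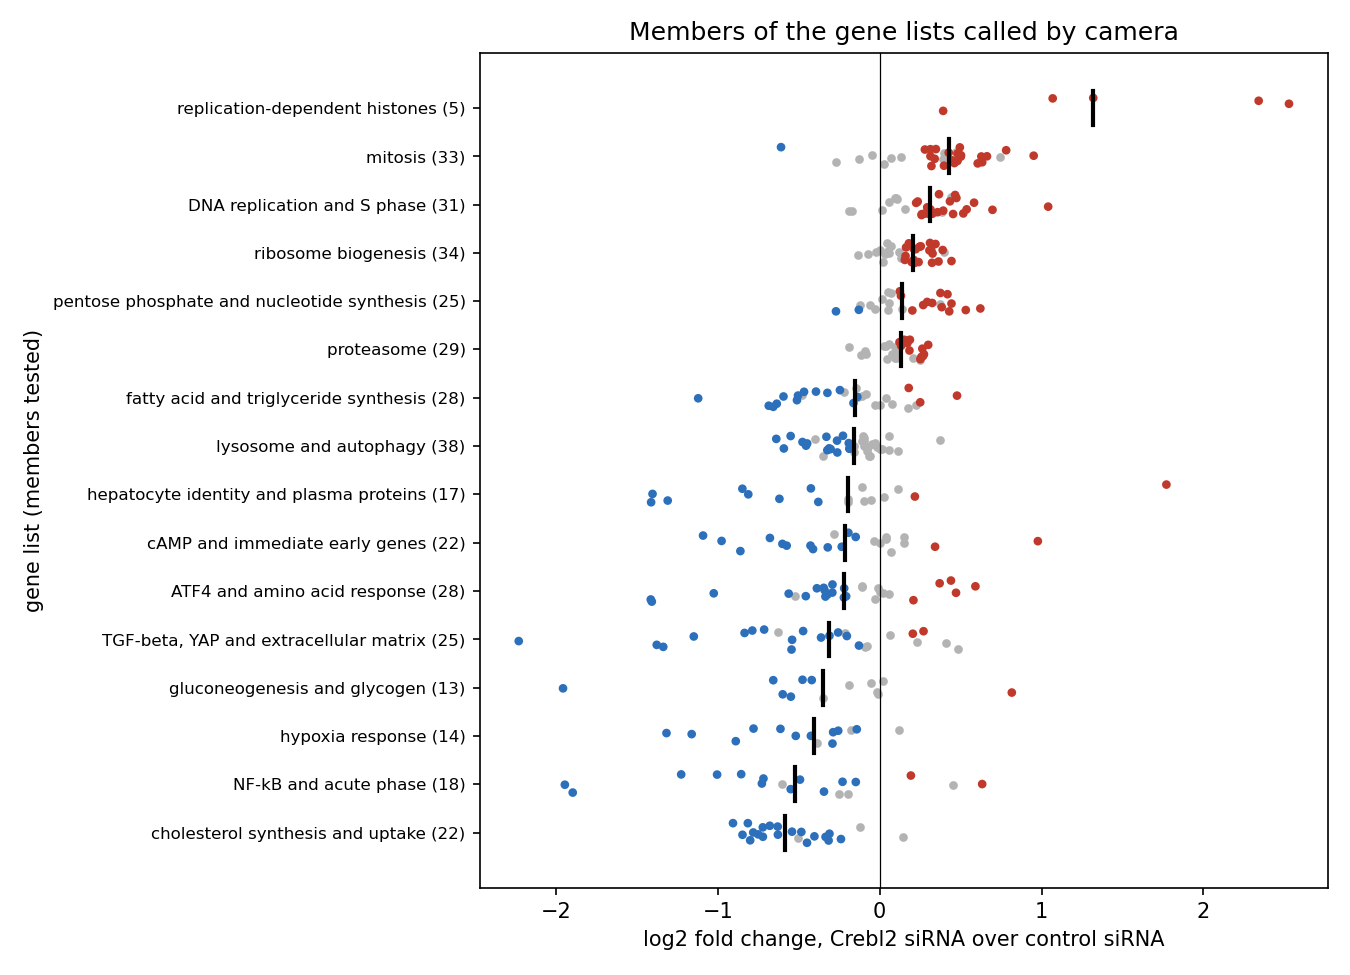
Each row is 1 of the 16 gene lists called by camera with the preset correlation, with members tested in brackets, and the x axis is the log2 fold change, Crebl2 siRNA over control siRNA. Points are genes (red raised, blue lowered, grey not called) and black bars are list medians, which run from -0.58 for cholesterol synthesis and uptake to 1.32 for histones.

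Genes of mitochondrial energy metabolism mostly did not pass the test. In the tricarboxylic acid cycle, 1 of 23 genes rose and 5 fell (1 and 4 when adjusted over the list alone; camera adjusted p = 0.718). Of 49 nuclear respiratory chain subunits, 8 rose and 4 fell (6 and 4 when adjusted over the list alone; camera adjusted p = 0.803), and of 25 fatty acid oxidation and ketogenesis genes, 2 rose and 6 fell, the same when adjusted over the list alone (camera adjusted p = 0.803). The oxidation list had a median of 0.02 and a mean of -0.02 in log2 fold change, with a downward test, and the respiratory list a median of 0.02 and a mean of -0.01, with an upward test. Pdha1, a pyruvate dehydrogenase subunit, fell by 0.35 and the uncoupling protein Ucp2 by 0.44 on the log2 scale, while Ndufa7 rose by 0.40.

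Mitochondrially encoded mRNAs had a median log2 fold change of -0.50, with 4 of 10 lowered (4 when adjusted over the list alone) and no call for the list (camera adjusted p = 0.0747). Mitochondrial genes took 2.31, 2.48 and 2.52% of counts in the control libraries and 2.23, 0.859 and 2.09% in the Crebl2 siRNA libraries, so that 1 library, replicate 2, stood apart. The exact permutation test of these shares gave p = 0.1, the smallest possible. Without that replicate 5 members fell, the median was -0.21 and the list was called (camera adjusted p = 0.0095). It was called in 8 of 18 alternative settings, whose adjusted p ran from 0.00118 to 0.845. The others were the runs without Crebl2 siRNA replicate 1 (0.0133), with the replicate block (0.0299), the GC and length offset with that block (0.0294), library size scaling (0.0361), no filter (0.0355), limma-voom (0.0250) and its sample weights (0.00118). mt-Nd2 (-0.76) and mt-Nd1 (-0.66) were called by edgeR (adjusted p = 0.0131 and 0.0208) but not by DESeq2 (0.114 and 0.155).

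None of the 16 list calls held with an estimated correlation, under which 5 of 35 lists had an unadjusted p under 0.05, whereas fry called 23 lists, these 16 among them. The counts of single genes within lists do not rest on that choice. A limit on the lowered genes is a 7-base word, GAAATGT, present in the annotated 3' UTR of 636 of 2169 lowered, 957 of 5696 uncalled and 225 of 1878 raised genes searched. These counts are not adjusted for 3' UTR length, whose median was 1392 bases in lowered, 1014.5 in uncalled and 1001.5 in raised genes. The word occurs in Gng12, Pla1a, Npr3, Ccn1, Ccn2, Epas1, Egln3, P4ha1, Cyp51, Nsdhl, Stard4, Ppp1r3c, Pck2, Icam1, Crebzf and Pdha1 among the lowered genes named. With all genes that hold it left out, a choice made after seeing the data, the gluconeogenesis and glycogen list was no longer called (adjusted p = 0.0961), the glycolysis list was (0.0344), and 14 of 17 sterol genes were still lowered.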

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

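The counts were recomputed under the alternative settings and under 3 more chosen after seeing the data, namely transcript rows, the mitochondrial share as a covariate and removal of genes with a 3' UTR word. Genes changed ran from 2926 to 5729, genes raised from 1320 to 2832, genes lowered from 1606 to 2897 and genes changed at least 2-fold from 254 to 665. The first 3 ranges leave out the test against a 1.2-fold change, which asks for more than a difference and called 1626 genes, 709 raised, 917 lowered and 394 changed at least 2-fold. With the mitochondrial share as a covariate, 2926 genes changed and 1320 rose, and mt-Nd5 and mt-Nd6 turned from lowered to log2 fold changes of 0.013 and 0.022 that were not called, since the covariate is their own summed share. A filter of at least 1 CPM in 3 libraries left 254 genes changed at least 2-fold, because it tests 9671 genes and drops low counts, whereas no filter tested 21321 genes and gave 665. Leaving out 1 library gave 3639 to 4640 genes changed (3677 without Crebl2 siRNA replicate 2, whose mitochondrial share was low), 456 to 558 changed at least 2-fold and 16 to 18 lists called. Crebl2 kept a log2 fold change between -1.94 and -1.85 under every alternative run.

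The number of gene lists called was 0 with camera at an estimated correlation, where 5 lists had an unadjusted p under 0.05, and 23 with fry. The cause of that difference was not tested. For the lost calls of the DNA replication and NF-kB lists, correlation above the preset 0.01 cannot be the cause. Their estimated correlations were -0.029 and -0.022, yet their unadjusted camera p rose from 2.4e-08 to 0.00312 and from 7.51e-05 to 0.0128. All other called lists had estimated correlations above 0.01. Of the 35 lists, 29 kept their call or lack of one with the preset correlation under every alternative run, but 10 lists without a call had medians that turned sign, apoptosis and the tricarboxylic acid cycle among them. The exceptions were glycolysis, gluconeogenesis, mitochondrial mRNAs, hepatocyte identity, histones and siRNA machinery. Without a filter the hepatocyte and histone lists lost their calls (adjusted p = 0.054 and 0.0542). Of 172 named genes apart from Crebl2, 161 kept their call or lack of one, and the 11 others include the 4 mitochondrial mRNAs.

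The replicate numbers did not pair the libraries. Deviations from the group means correlated at -0.13, -0.04 and -0.08 between libraries of equal number, no better than between others, and the fit with the replicate block called 3983 genes. With a GC and length offset the counts were 5438 genes without the replicate block and 5243 with it. DESeq2 called 4106 genes, 4098 of them shared with edgeR. Simulated changes of 1.5-fold were found in 68.7% of cases, but only 200 of 11616 genes were changed there. With 4518 genes called, the adjustment sets a looser cutoff in the libraries themselves, so that share does not carry over to this comparison.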

Other observations

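Of the explanations weighed below, the tests of base content, neuronal RNA, REST targets, library distance and other splits were chosen after the result was seen. Cell type markers beyond hepatocytes gave no common direction across cell types. Of 5 cholangiocyte markers with enough counts, 2 rose and 2 fell (3 and 2 when adjusted over the list alone), with keratin Krt7 lower (log2 fold change -0.56) and Krt19 higher (0.30), and the list was not called (camera adjusted p = 0.978). Fibroblast, macrophage, endothelial and myoblast markers had 3, 3, 2 and 2 members with enough counts and no list test. Among these Dcn (-0.55), Stab1 (-0.70), Cd14 (-0.61) and Lyz2 (-0.84) fell and Des (0.35) and Vwf (0.72) rose. Of the 3 macrophage and leukocyte markers 2 thus fell and 0 rose. Lyz2 lost its call without control replicate 2 or 3 and with the mitochondrial share as a covariate. Of 14 genes of the siRNA and microRNA machinery, 8 rose and 2 fell (9 and 2 when adjusted over the list alone), with Dicer1 at 0.29 and Xpo5 at 0.28 raised and Prkra lowered (-0.33). That list was not called (camera adjusted p = 0.108), except without control replicate 1 (0.0389) and with sample weights (0.0271), the adjusted p reaching 0.281 in other alternatives.

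Other lists moved in both directions and were not called by camera. Of all genes tested, 38.9% were called, so a share of called members near that does not set a list apart. Of 21 CREB-like factors and partners, 3 rose and 6 fell (adjusted p = 0.376), with the circadian factors Hlf raised (log2 fold change 1.62) and Dbp (-1.06) and Tef (-0.62) lowered. Xenobiotic and bile acid genes showed 4 raised and 5 lowered of 13 (adjusted p = 0.803), with Cyp1b1 raised (0.88) and its regulator Ahr lowered (-0.61). Of 23 NRF2 and oxidative stress genes, 8 rose, Gsr (0.72) and Nqo1 (0.78) among them, and 6 fell (adjusted p = 0.99). Of 27 interferon response genes, 3 rose and 8 fell, with Rsad2 at 0.89 and Ifit2 at -0.61 (adjusted p = 0.481). Apoptosis regulators had 4 raised and 6 lowered of 18 (adjusted p = 0.751), Mcl1 (-0.87) and Bmf (-1.01) lowered and Bok (1.28) raised, and p53 targets 5 raised and 3 lowered of 20 (adjusted p = 0.711), Gadd45a at -1.08. mTORC1 components had 6 raised and 5 lowered of 32 (adjusted p = 0.82), with Castor1 (0.70) and Deptor (0.57) raised and Sesn3 lowered (-0.48). Of these lowered genes Ahr, Mcl1, Ifit2 and Sesn3 hold the word GAAATGT in the 3' UTR. Insulin and FoxO targets had 3 raised and 5 lowered of 15 (adjusted p = 0.803), and all 5 lowered hold that word. Without genes that hold it, 3 insulin targets rose and 0 fell of 7 (median log2 fold change 0.16, camera adjusted p = 0.0754). Endoplasmic reticulum stress genes had 3 raised and 8 lowered of 23 (adjusted p = 0.823). Lipid droplet and lipoprotein genes had 3 and 3 of 13 (0.718) with Lpl raised (0.76), and fetal liver genes 2 and 2 of 8 (0.288) with Gpc3 lowered (-0.87). Counts adjusted over the list alone differed only for insulin targets (3 and 6), NRF2 (8 and 7), interferon (4 and 9) and fetal liver genes (4 and 2). Medians and tests had opposite signs for the stress list (0.04, downward) and insulin targets (0.02, downward), and mean and median did for the xenobiotic (0.15 and -0.09), NRF2 (0.07 and -0.08), p53 (-0.02 and 0.04) and cholangiocyte (-0.13 and 0.14) lists. When transcript rows were tested singly, 17 genes had called rows in opposite directions. Pkm, chosen after its values were seen, had rows at -0.22 and 0.26.

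Genes with GAAATGT in the 3' UTR were lower than others by 0.127 on the log2 scale (1818 genes of 9743), the lowest z (-10.5) of 15270 words, where 100 permutations reached -5.13. Base content does not account for it, since the 209 other words of the same bases reached a z of -3.58 at most. Nor does 1 Crebl2 siRNA library, since the weakest of the 3, each against the control mean, gave -11.3. A single control library was not tested, as all 3 values share that mean. Genes with 2 or more copies lay below genes with 1 copy by a further -0.122 (SE 0.0238), as silencing through a guide strand seed would predict. The word occurs once in the Crebl2 transcript, at base 484 in its coding sequence. Of the words tested, 19.6% occur at least once anywhere in that transcript of 3629 bases. Seed-driven silencing by the Crebl2 siRNA is a candidate source of part of the fall. The siRNA sequence and microRNAs of the cell were not analysed here.

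Srrm3, Disp2 and Svop, with Chrnb2 chosen after its values were seen, are genes otherwise known from neurons. For RNA from neuronal cells, 6 abundant neuronal transcripts summed to 0.0599 CPM in the Crebl2 siRNA libraries against 10.5 CPM for Srrm3. Counts of different genes are not comparable as abundances here, so this sum cannot decide whether neuronal RNA was present. A general release of targets of the repressor REST stays open. Of 46 other REST targets listed after the rises were seen, 12 had enough counts, 4 rose and 2 fell, and their median log2 fold change of 0.28 lay at percentile 95.9 of 10000 lists matched on expression. Few tested members keep it open, and the rise may equally be a consequence of Crebl2 loss, which was not tested separately.

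Crebl2 siRNA replicate 2 had a low mitochondrial share, with all 9 mitochondrial genes of 300 or more counts at 0.363 to 0.618 of the mean of its partners. Whether its other RNA differed stays open. Over genes of at least 1 CPM its root mean square log2 distance from its partners, 0.178, was the smallest of the 3, but it had the most genes detected (17960, against 16955 to 17308) and the highest long non-coding RNA share (1.19%, against at most 1.13%) of the 6 libraries. Genomic DNA is argued against, since counts in 1432 olfactory and vomeronasal receptor genes were, as a share of the total, 1.04 times those of the highest other library. What lowered the share was not found, and no biological explanation was tested.

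The 6 libraries can be divided 3 against 3 in 10 ways, too few for a share of splits under 0.05, and for each count 1 split, the real one, gave a result as large. The real split called 4518 genes changed, 2180 raised, 2338 lowered and 448 changed at least 2-fold by edgeR, and the highest of the 9 other splits was 0 for each, with 74 to 411 genes at an unadjusted p under 0.05. For gene lists the real split called 16 and the highest other split 11. Each other split mixed both treatments on each side, which added the treatment difference to the spread within sides. Few or no called genes were therefore fixed in advance there, and the comparison cannot show how many genes chance would call.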
